A study of Mus musculus with 6 samples.

How the data were processed

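RNA was sequenced from subcutaneous tumours that grew from DU145 cells, a human prostate cancer line, in male nude mice. The sample titles and columns of the treated group carry MBZ, the treatment label and the series design give Zelnorm, and what MBZ stands for is not given in the sources used here. The group is called Zelnorm as labelled, so every comparison is between the labelled groups. Per the labels' protocols, the mice were assigned at random once tumours could be felt, Zelnorm (tegaserod, an agonist of the serotonin receptor HTR4) was given by mouth every day, and libraries were made from total RNA with a TruSeq kit. The labels give no dose. There were 3 control tumours and 3 Zelnorm tumours. The labels describe the 6 samples as separate tumours of 2 groups but do not name the animals, so p-values of single genes measure the spread between these samples.

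The deposited values are estimated counts per gene, which need not be whole, in one table of human genes and one of mouse genes for the same 6 libraries. Per the submitters' processing notes, HISAT2, StringTie, DESeq2, edgeR, GRCh38 and GRCm38 were used, with no versions or roles given. How reads were divided between the human and the mouse table is not given in the sources used here. Among values above 0, 38.0% in the human table and 27.0% in the mouse table were not whole. The tests had been planned for raw counts, and the estimated counts were therefore rounded to whole numbers first. Column names carry the group prefix of the sample titles and a number that no label repeats. Libraries are therefore named by column (controls NC10, NC4 and NC9; Zelnorm MBZ_254, MBZ_257 and MBZ_259) and were tied to a group but not to a replicate number. Rows without a gene name, 574 of 59458 human and 856 of 56392 mouse rows, stayed out of library sizes and tests. They held 0.407% to 0.518% of the counts of a library in the human table and 0.317% to 0.468% in the mouse table. Of the named mouse rows, 99.8% had an identifier in the GENCODE vM21 annotation of GRCm38, from which mouse coordinates were taken. No human coordinates are given.

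Depth was 24602178 to 39278195 counts per library in the human table and 5817165 to 9228446 in the mouse table. Intervals on shares (Wilson, 95%) and the floor of 3 counts for a gene with no counts cover counting error only.

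Zelnorm was compared with control in each table with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) after filterByExpr and TMM scaling within the table. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Fold changes are log2 of Zelnorm over control with a standard error (SE) derived from the F statistic. Levels are CPM, counts scaled to the library total of the tested genes of one table times its TMM factor. The floors of HTR4 and Htr4 were scaled to the total of the named genes without a factor. The 2 tables were never set on one scale. Gene lists (20 human and 27 mouse) and the comparisons, tests and thresholds of the results were fixed before the data were examined. The alternatives named as such below and most tests of the closing part were chosen later. Lists were tested with camera in limma 3.58.1, with an inter-gene correlation preset at 0.01, on log2 CPM with a prior count of 2, adjusted over the lists of a table. With the preset value, camera takes little account of members that move together from tumour to tumour, so its p-values do not measure that spread. Among called lists the estimated correlation ran from 0.000461 (classically activated macrophages) to 0.98 (skeletal muscle), with 0.546 for adipocytes. The test was repeated with an estimated correlation and with the directional test of fry, which asks only whether a list's genes move one way on balance. A list score is the mean over members of log2 CPM minus the gene's mean over the 6 tumours. The mouse share of counts was compared with an exact two-sided permutation test, whose smallest possible p is 0.1 for 3 against 3 tumours. Same-symbol gene pairs were tested for a different response in the mouse and the human table by an interaction term in edgeR, with the library as a block.

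Genes named in the text followed a rule fixed in advance. In each direction the rule takes the 12 genes with the largest change among called genes whose 3 Zelnorm libraries lie on one side of all 3 control libraries. They need a mean CPM of at least 1, a gene symbol that is not a clone or predicted name, and a same-symbol partner in the other table below 10 times their own mean count. Where fewer than 5 qualify, the uncalled genes with the smallest p that meet the other conditions fill up to 5, given as values. The rule adds up to 4 members with the smallest p from each list, HTR4 and Htr4, and up to 5 gene pairs per direction. Other genes named were chosen after their values were seen, and this is said where they appear. The result of 1 gene that the rule selects is not reported here.

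Each procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold at these depths and spreads. The changed genes were drawn from those above a minimum average level, so recovery among genes of low level was not tested. In the human table (18820 genes) edgeR recovered 64 of the 2-fold and 99 of the 4-fold changes. In the mouse table (14459 genes) it recovered 9 and 81, and the interaction test (11154 pairs) 13 and 90. In the human table edgeR also called 15 unchanged genes and DESeq2 39, beside 82 and 98 changed genes recovered by DESeq2. In the mouse table edgeR called 6 unchanged genes and DESeq2 29, beside 28 and 86 recovered. A DESeq2 call is thus less strict at these depths. The largest list, shifted 1.5-fold, was recovered by camera in each table, with 0 other lists called. Simulated genes were drawn independently of each other, so this cannot show how often camera calls lists whose genes move together.

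Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper-quartile factors, library sizes taken from both tables without a factor, no count filter (at least 1 count in total), a filter of 50 counts in 3 libraries, the mouse share as a covariate, leaving out genes whose partner in the other table had at least as many counts, a log2 fold change of at least 1, and leaving out each library in turn. The mouse share was recomputed on filtered genes, without genes that have a partner and without mitochondrial genes. The pair test was repeated without the library block, with the stricter filter, with RLE factors and with pairs within a ratio of 10. Alternatives chosen after the data had been seen were the restriction to genes whose partner had under 0.1 of their counts and the removal of both NC4 and MBZ_257. Partners were matched by symbol in capitals. A gene without a match was treated as having no partner counts, so a partner under another symbol was missed. Of the tested mouse genes, 70.1% had a human partner with at least as many counts, and these genes held 73.1% of the mouse counts of tested genes, so human reads placed in the mouse table would weigh on them most. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.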

Results

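The study asked how oral Zelnorm acts on a prostate tumour and on its immune surroundings. The sample titles call the treated group MBZ and the treatment label calls it Zelnorm, and Zelnorm here means the group so labelled. Each of the 6 tumours was read in a human table, meant for the DU145 cells, and in a mouse table, meant for the host's immune cells, vessels and connective tissue. The human table held 25854118, 26736397 and 39278195 counts for the controls NC10, NC4 and NC9, and 24602178, 32731649 and 36935816 for the Zelnorm tumours MBZ_254, MBZ_257 and MBZ_259. The mouse table held 6158251, 7653012 and 9228446 counts for the controls and 7503977, 5817165 and 9050985 for the Zelnorm tumours, in the same order. Pairs of libraries of the same group were as alike as pairs of different groups. The mean Pearson correlation across genes was 0.982 within and 0.983 between groups in the human table, and 0.943 within and 0.947 between groups in the mouse table, with genes not being independent replicates.

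The mouse table held 20.2% ± 1.81 of the counts of both tables in the control tumours and 19.4% ± 4.15 in the Zelnorm tumours (SD, n = 3 each). The difference of -0.79 percentage points was smaller than the spread between tumours (exact two-sided permutation p = 1, smallest possible p 0.1). Among the controls the share was 19.2% in NC10 (95% Wilson interval 19.22 to 19.25), 22.3% in NC4 (22.24 to 22.27) and 19.0% in NC9 (19.01 to 19.04). Among the Zelnorm tumours it was 23.4% in MBZ_254 (23.36 to 23.39), 15.1% in MBZ_257 (15.08 to 15.10) and 19.7% in MBZ_259 (19.67 to 19.69). The sign of the difference turned without NC4 (0.25 points) or without MBZ_257 (1.35 points).

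**Figure D1:**
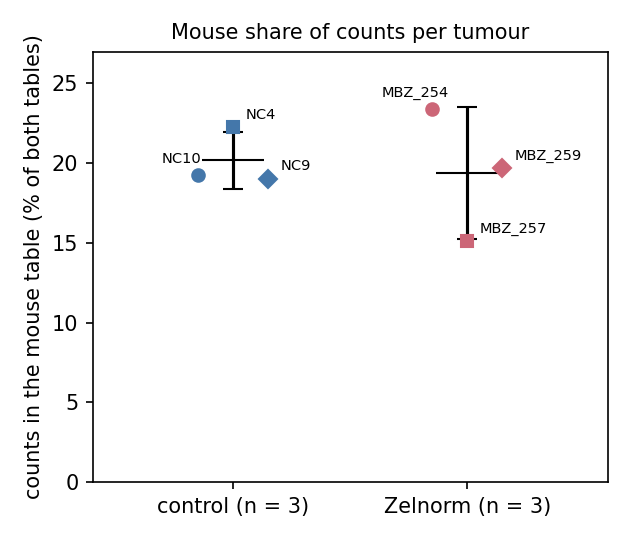
Counts in the mouse table as a percentage of the counts of both tables (vertical axis), one point per tumour, with the group mean and SD as horizontal and vertical bars. The Zelnorm tumours span 15.1% to 23.4% and enclose all 3 controls.

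Transcripts of HTR4, the serotonin receptor of which tegaserod is an agonist, were at or under the limit of detection. HTR4 had 1 count in NC4 and none in the other human libraries, where 3 counts would correspond to 0.077 to 0.122 CPM. Htr4 had no count in the 6 mouse libraries, where the same floor lay at 0.327 to 0.517 CPM. Neither gene could be compared between groups at this depth. In the human list of serotonin receptors and handling, 9 genes were measurable and as a group did not differ (5 higher, 4 lower; camera adjusted p = 0.737). HTR1D, another serotonin receptor, had a log2 fold change of 0.19 (SE 0.26), and other members of the list had a smaller p. The list's median and mean fold change were above 0 while the test pointed lower. Of the mouse list 7 genes were measurable, 3 higher and 4 lower (adjusted p = 0.829). Maoa, which encodes a serotonin-degrading enzyme, was at 21.6 ± 1.51 CPM in control and 18.5 ± 1.34 CPM in Zelnorm tumours. It was not the member of the mouse list with the smallest p.

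In the human table, the genes with the smallest p on the higher side were CXCL2, CLEC18C, DUSP1, CXCL8 and TIPARP. CXCL2, a chemokine that attracts neutrophils (ENSG00000081041), was at 6.33 ± 0.76 CPM in control and 11.9 ± 3.24 CPM in Zelnorm tumours (SD, n = 3), a log2 fold change of 0.92 (SE 0.22). CXCL8, a chemokine of the same family (ENSG00000169429), was at 7.47 ± 1.04 and 12.9 ± 4.26 CPM (log2 0.78, SE 0.24). DUSP1, a phosphatase that switches off MAP kinases (ENSG00000120129), was at 61.7 ± 2.31 and 148 ± 96.4 CPM. Its Zelnorm mean rested on MBZ_259 at 259 CPM, against 82.2 in MBZ_254 and 103 in MBZ_257, and without MBZ_259 its log2 fold change went from 1.26 to 0.59. TIPARP had a log2 fold change of 0.43 (SE 0.13) and CLEC18C of 1.42 (SE 0.35). On the lower side TMEM238 (ENSG00000233493) was at 2.91 ± 1.10 CPM in control and 0.68 ± 0.17 CPM in Zelnorm tumours (log2 -2.09, SE 0.36). CHCHD10, a mitochondrial protein, had a log2 fold change of -0.90 (SE 0.26), EBPL of -0.52 (SE 0.14), P3H3 of -0.51 (SE 0.16) and FAM53B of -1.51 (SE 0.48). The log2 fold change of FAM53B ran from -2.34 without MBZ_254 to -0.83 without both NC4 and MBZ_257. P3H3 and FAM53B had more counts for the same symbol in the mouse table. The rule that named these 10 genes requires all 3 Zelnorm libraries on one side of all 3 control libraries. Of all tested human genes 4.82% met that condition, where chance gives 10%.

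None of these genes passed the test over all genes. Of 18820 human genes, edgeR's quasi-likelihood test called 0 (smallest adjusted p = 1.00), with 247 at an unadjusted p under 0.05 where 941 would be expected by chance. DESeq2 called 2, both lower: TMEM238 (adjusted p = 0.0123) and AC026464.4 (adjusted p = 0.0164), which had 31, 20 and 10 counts in the controls and 0 in each Zelnorm library. limma-voom called 0, but with 1069 genes at an unadjusted p under 0.05, so the count below the number expected by chance depended on the tool. Without the count filter edgeR called 61 genes, 42 higher and 19 lower, among them CXCL2, DUSP1 and TMEM238. Over all alternatives the adjusted p ranged from 0.0156 to 1.00 for CXCL2, from 6.64e-10 to 1.00 for DUSP1 and from 1.39e-05 to 1.00 for TMEM238.

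As a group, NF-kB targets and cytokines lay higher in the Zelnorm tumours. Of 17 measured members 15 were higher (camera adjusted p = 7.97e-06; adjusted p = 0.749 with an estimated correlation), with a median log2 fold change of 0.32. Adjusted over the list alone, 1 member passed: CXCL2 (edgeR adjusted p = 0.0336). Besides CXCL2 and CXCL8, CCL20 had a log2 fold change of 1.35 (SE 0.51) and NFKBIA, the inhibitor that NF-kB induces, of 0.32 (SE 0.14). All 20 cholesterol synthesis genes were higher (adjusted p = 0.00014; adjusted p = 0.75 with an estimated correlation), with a median log2 fold change of 0.16, but the score of the Zelnorm tumour MBZ_254 was the lowest of the 6 at -0.17. All 22 ribosomal protein genes were higher by small amounts (median log2 fold change 0.10; adjusted p = 0.000431; adjusted p = 0.749 with an estimated correlation). All 21 hypoxia and glycolysis genes were higher (median 0.15; adjusted p = 0.0363; adjusted p = 0.75 with an estimated correlation), but the score of MBZ_259 was the lowest of the 6 tumours at -0.37 and that of MBZ_254 the highest at 0.54. Without MBZ_254 the list's mean turned to -0.08.

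Interferon response genes lay lower, 22 of 25 (median log2 fold change -0.21; camera adjusted p = 0.0394; adjusted p = 0.75 with an estimated correlation). Their scores differed within both groups by more than between them, from -0.53 to 0.46 among controls and from -0.58 to 0.32 among Zelnorm tumours. MX1, an antiviral GTPase, was at 109 ± 28.2 CPM in control and 84.8 ± 28.6 CPM in Zelnorm tumours. Adjusted over the list alone, 0 members of the cholesterol, ribosomal, hypoxia and interferon lists passed. With an estimated correlation, 0 of the 20 human lists passed, and fry called 0. Leaving out NC9 left 1 list called and leaving out MBZ_257 gave 10. Adjusted p-values of these 5 lists over all alternatives ranged from 1.33e-09 to 0.947.

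**Figure D2:**
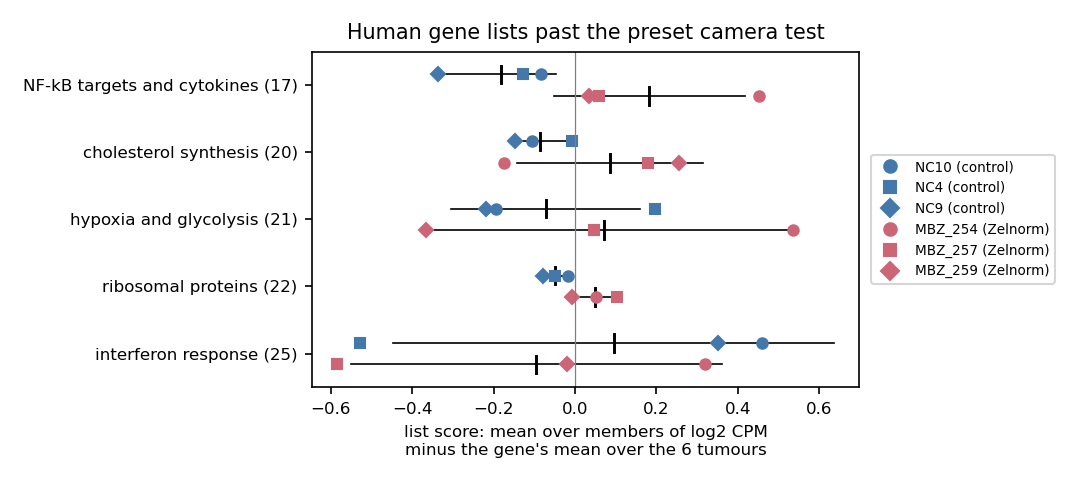
Scores of the 5 human lists past the camera test with the preset correlation (horizontal axis, log2 units), one symbol per tumour, controls above Zelnorm in each row, with group means (vertical bars) and SD (horizontal lines). The number of measured genes follows each name. The NF-kB scores of the Zelnorm tumours, 0.03 to 0.45, all lie above those of the controls, -0.34 to -0.08. So do the ribosomal protein scores, -0.008 to 0.10 against -0.08 to -0.02, while the cholesterol, hypoxia and interferon scores of both groups overlap.

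Cell division and stress lists of the human table did not pass. Mitosis genes were lower in 23 of 25 members (adjusted p = 0.0785) and DNA replication genes in 16 of 24 (adjusted p = 0.291). CENPF, a kinetochore protein, was at 93.3 ± 26.9 CPM in control and 76.7 ± 10.1 CPM in Zelnorm tumours. Of the p53 targets 12 of 20 were higher (adjusted p = 0.163), with CDKN1A, the cell cycle inhibitor p21, at 39.8 ± 1.62 and 53.8 ± 10.3 CPM. The unfolded protein and integrated stress response had 13 of 20 members higher (adjusted p = 0.11), oxidative phosphorylation 20 of 22 (adjusted p = 0.11) and squamous differentiation and keratins 11 of 15 (adjusted p = 0.163). Apoptosis regulators had 15 of 23 higher (adjusted p = 0.213), tubulins 10 of 13 (adjusted p = 0.266) and PI3K and STAT3 feedback genes 13 of 19 (adjusted p = 0.344). Antigen presentation had 15 of 20 members lower (adjusted p = 0.23) and NRF2 targets 12 of 21 (adjusted p = 0.243). Luminal keratins and the androgen axis (adjusted p = 0.566), immune checkpoint and NK ligands (adjusted p = 0.746) and epithelial-mesenchymal transition (adjusted p = 0.79) were the lists with the largest adjusted p beside serotonin handling. For the checkpoint and transition lists the median log2 fold change was below 0 and the mean above 0, and the tests pointed higher for the checkpoint list and lower for the transition list.

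In the mouse table the list with the smallest p was that of fat cell genes, which lay lower in the Zelnorm tumours. All 17 measured adipocyte genes were lower, with a median log2 fold change of -1.25 (camera adjusted p = 2.71e-15; adjusted p = 0.523 with an estimated correlation). Adjusted over the list alone, 9 passed edgeR's test: Retn, Cfd, Fasn, Cidec, Plin4, Lipe, Plin1, Adipoq and Car3, of which Plin4, Lipe, Plin1, Adipoq and Car3 lay outside the naming rule. Retn, which encodes the fat hormone resistin (ENSMUSG00000012705, chromosome 8 from 3655770 to 3660110 in GRCm38), was at 7.33 ± 2.10 CPM in control and 1.85 ± 0.85 CPM in Zelnorm tumours (SD, n = 3; log2 -2.02, SE 0.44). Cfd, the adipocyte protease adipsin (ENSMUSG00000061780, chromosome 10 from 79890853 to 79892655), was at 152 ± 75.0 and 27.6 ± 17.6 CPM (log2 -2.47, SE 0.56). Cidec, a lipid droplet protein, had a log2 fold change of -2.63 (SE 0.74) and Fasn, fatty acid synthase, of -1.16 (SE 0.29). Cidec was at 58.6 CPM in NC4, against 10.1 and 20.4 in the other controls. With 1 library left out, its log2 fold change ran from -3.51 without MBZ_254 to -1.67 without NC4. That of Cfd was -3.07 without MBZ_254. The adipocyte score was 0.64 ± 0.63 in control and -0.64 ± 0.55 in Zelnorm tumours, and the lowest control (NC10, 0.04) lay above the highest Zelnorm tumour (MBZ_254, -0.15). The control NC4 had the highest score, 1.31, and without it the mean log2 fold change of the list was -0.87 in place of -1.28. Over all alternatives the list's adjusted p ranged from 2.27e-19 to 0.816.

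The mouse genes with the smallest p on the lower side were Cyp2e1, Glb1l2, Cdo1, Apoc1 and Pon1. Cyp2e1, a cytochrome P450 (ENSMUSG00000025479, chromosome 7 from 140763739 to 140774987 in GRCm38), was at 62.7 ± 44.9 CPM in control and 4.25 ± 1.93 CPM in Zelnorm tumours (SD, n = 3; log2 -3.92, SE 0.57). Its control mean rested on NC4 at 114 CPM, against 28.7 in NC10 and 45.7 in NC9, and without NC4 its log2 fold change was -3.16. Cdo1, cysteine dioxygenase, was at 12.9 ± 3.48 and 3.47 ± 0.83 CPM (log2 -1.90, SE 0.32). Glb1l2 had a log2 fold change of -2.77 (SE 0.43), Apoc1, an apolipoprotein, of -2.32 (SE 0.47) and Pon1, paraoxonase, of -3.11 (SE 0.66), which went to -4.30 without MBZ_257. On the higher side, Arg2, a mitochondrial arginase (ENSMUSG00000021125, chromosome 12 from 79130777 to 79156301), was at 2.69 ± 0.07 CPM in control and 6.18 ± 0.60 CPM in Zelnorm tumours. Il1rn, the antagonist of the interleukin-1 receptor, was at 10.2 ± 2.24 and 20.5 ± 5.22 CPM, and Uck2 had a log2 fold change of 0.53 (SE 0.13). Apoc1, Pon1, Glb1l2, Arg2, Uck2 and the adipocyte gene Fasn had more counts for the same symbol in the human table. H2-T-ps, a pseudogene of the major histocompatibility complex (MHC), and Pagr1b, which overlaps its near-identical copy Pagr1a, are uncertain. Pagr1b had 0 counts in each control and 18, 15 and 19 in the Zelnorm libraries, while Pagr1a and Pagr1b together had 0, 22 and 6 against 33, 17 and 25.

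None of 14459 mouse genes passed edgeR's quasi-likelihood test (smallest adjusted p = 1.00), with 253 at an unadjusted p under 0.05 where 723 would be expected by chance. DESeq2 called 6. Cyp2e1 (adjusted p = 3.65e-11), Glb1l2 (adjusted p = 0.00017), Cdo1 (adjusted p = 0.0109) and Thrsp, a lipogenic regulator (adjusted p = 0.0114), were lower, and Pagr1b (adjusted p = 0.0114) and Tspan32 (adjusted p = 0.0114) higher. Tspan32 and Thrsp lay outside the naming rule, and Tspan32 had 0 counts in each control and 51, 1 and 52 in the Zelnorm libraries. limma-voom called 1 gene (Pagr1b), with 1038 at an unadjusted p under 0.05, above the number expected, and edgeR without the count filter 2 (Cyp2e1 and Glb1l2). Over all alternatives the adjusted p of Cyp2e1 ranged from 3.65e-11 to 1.00, and that of Glb1l2 from 0.00017 to 1.00.

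Macrophage genes lay slightly higher in the Zelnorm tumours. Of 19 measured members 16 were higher, with a median log2 fold change of 0.18 (camera adjusted p = 0.00226; adjusted p = 0.523 with an estimated correlation). Lyz2, lysozyme of myeloid cells (ENSMUSG00000069516), was at 1534 ± 243 CPM in control and 2144 ± 273 CPM in Zelnorm tumours (log2 0.48, SE 0.20). Markers of classical activation were higher in 12 of 16 (adjusted p = 0.0333; adjusted p = 0.523 with an estimated correlation), with Il1b, an inflammatory cytokine, at 34.5 ± 12.2 and 66.2 ± 35.5 CPM. Without MBZ_254, which had the highest score of both lists, neither was called. Over 18 alternatives the macrophage list lost its call in 5 and the classical activation list in 9. Markers of alternative activation went both ways, 7 higher and 9 lower (adjusted p = 0.979): Ccl22, a chemokine, had a log2 fold change of 1.15 (SE 0.39) and Cd209d, a lectin, of -1.59 (SE 0.70), whose control mean rested on NC4 (16.6 CPM, against 4.65 in NC10 and 3.91 in NC9). All 9 MHC class II genes were higher (adjusted p = 0.00295; adjusted p = 0.523 with an estimated correlation), and Cd74, the invariant chain, was at 1650 ± 566 CPM in control and 2050 ± 357 CPM in Zelnorm tumours. H2-Eb1, a member of this list, was near absent in 1 library of each group, with 56 counts in NC10 and 47 in MBZ_259 against 1562 to 3486 in the other libraries. The MHC class II call was lost without NC4 or without MBZ_254, and with limma-voom the list's mean log2 fold change was -0.15 (adjusted p = 0.852; 4.69e-06 to 0.852 over the alternatives).

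Natural killer cell genes lay lower, 9 of 12, with a median log2 fold change of -0.39 (camera adjusted p = 0.00295; adjusted p = 0.523 with an estimated correlation). Xcl1, a chemokine of these cells, was at 3.03 ± 0.97 CPM in control and 0.98 ± 0.47 CPM in Zelnorm tumours, and Gzmc, a granzyme, at 11.2 ± 4.35 and 6.57 ± 0.73 CPM. The call was lost without NC9 or without MBZ_257. Of the B and plasma cell genes 5 of 7 were higher (adjusted p = 0.0294; adjusted p = 0.523 with an estimated correlation), with Igkc, the kappa light chain, at 2.12 ± 2.37 CPM in control and 51.7 ± 81.8 CPM in Zelnorm tumours. The Zelnorm mean of Igkc rested on MBZ_254 at 146 CPM, against 0.185 in MBZ_257 and 8.91 in MBZ_259, and without MBZ_254 its log2 fold change went from 4.51 to 1.09. This list was no longer called without NC10, NC9 or MBZ_254. T cell and NK checkpoint genes were higher in 6 of 11 (adjusted p = 0.0284; adjusted p = 0.523 with an estimated correlation). Pdcd1lg2, the checkpoint ligand PD-L2, was at 0.647 ± 0.005 and 2.12 ± 0.48 CPM (log2 1.69, SE 0.44). It had a mean of only 10.3 counts per library, so the small control SD need not mean a precise level. The call of the checkpoint list was lost without NC4, NC9 or MBZ_254. Of the T cell genes 6 of 20 were measurable, all 6 higher (adjusted p = 0.121). Their score was 0.75 in MBZ_254 but -0.19 in MBZ_257 and -0.21 in MBZ_259, against -0.22 to -0.02 in the controls, so this rested on MBZ_254.

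Connective tissue, mast cell and blood genes lay lower. Fibroblast genes were lower in 17 of 20 members (median log2 fold change -0.40; camera adjusted p = 2.99e-05; adjusted p = 0.523 with an estimated correlation) and collagens and matrix genes in 21 of 24 (median -0.21; adjusted p = 0.00626; adjusted p = 0.756 with an estimated correlation). Pi16, a marker of adventitial fibroblasts, was at 151 ± 50.1 CPM in control and 85.0 ± 17.1 CPM in Zelnorm tumours, and Col3a1, a fibrillar collagen, had a log2 fold change of -0.54 (SE 0.42). Members of the collagens and matrix list with a smaller p than Col3a1 went both ways, and the member with the smallest p was higher. MBZ_257 had the lowest score of both lists (-0.96 and -0.72) and NC4 the highest (0.66 and 0.44), and neither list was called lower without either library. Without both NC4 and MBZ_257, chosen after the data were seen, the collagens and matrix list was called higher (mean log2 fold change 0.25; adjusted p = 0.000397, with 0.000364 to 0.933 over the alternatives). Mast cell genes were lower in 7 of 8 (median -1.04; adjusted p = 0.000128; adjusted p = 0.523 with an estimated correlation), with Tpsb2, a mast cell tryptase, at 12.6 ± 5.75 and 4.77 ± 2.05 CPM. All 6 red blood cell genes were lower (median -1.27; adjusted p = 0.000128; adjusted p = 0.523 with an estimated correlation), and Alas2, which starts haem synthesis in red cells, passed over the list alone (edgeR adjusted p = 0.048; log2 -1.63, SE 0.46; -0.80 without both NC4 and MBZ_257). Complement genes were lower in 13 of 18 (adjusted p = 0.00226; adjusted p = 0.523 with an estimated correlation), and 1 passed over the list alone, Cfd (edgeR adjusted p = 0.0415), which is also in the adipocyte list. Without NC4 the mean log2 fold change of the complement list went from -0.62 to -0.19 and that of the mast cell list from -0.86 to -0.46, and the complement call was lost without NC4 or without MBZ_257. Among the red blood cell genes Hba-a2, an alpha globin, was at 690 CPM in NC4, 99.9 in NC10 and 190 in NC9, and at 106 to 141 in the Zelnorm tumours, and without NC4 the mean of the red blood cell list went from -1.14 to -0.38. NC4 had the highest score of the mast cell, red blood cell and complement lists, and MBZ_257 the lowest. Without both libraries 11 mouse lists were called, 8 higher and 3 lower.

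Skeletal muscle genes differed between tumours rather than between groups. Their scores were -0.35, 2.57 and 2.23 in the controls NC10, NC4 and NC9, and -4.31, -3.89 and 3.75 in MBZ_254, MBZ_257 and MBZ_259. The list was called lower (camera adjusted p = 1.47e-07; adjusted p = 0.523 with an estimated correlation), although the median log2 fold change was 0.38 and the mean 0.25. Ckm, muscle creatine kinase, was at 142 ± 111 CPM in control and 248 ± 429 CPM in Zelnorm tumours. Cell proliferation genes of the mouse table were lower in 24 of 27 (adjusted p = 8.23e-07; adjusted p = 0.523 with an estimated correlation), with Mki67 at 84.1 ± 11.6 and 58.5 ± 2.23 CPM. All 27 had at least as many counts for the same symbol in the human table.

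**Figure D3:**
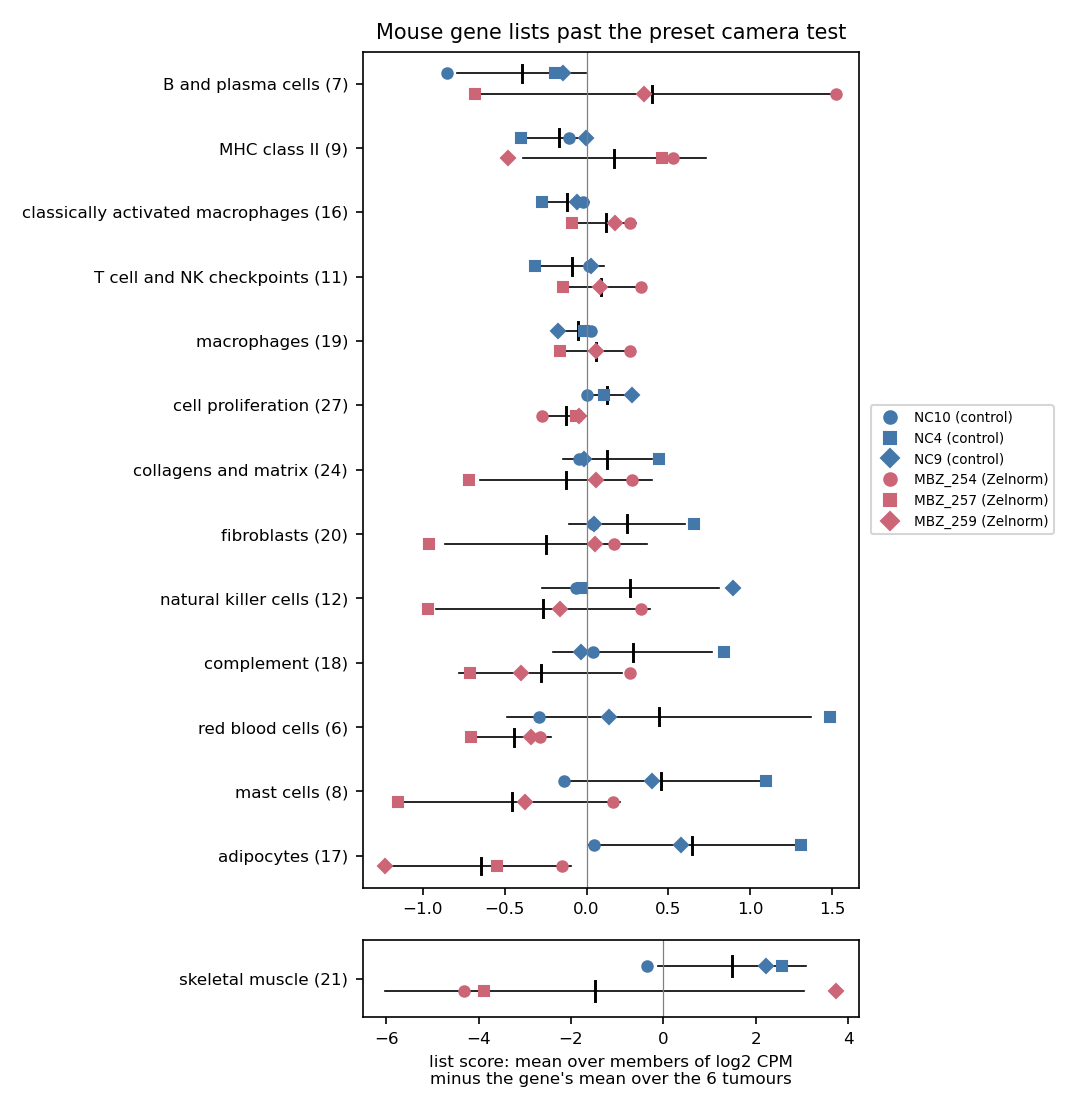
Scores of the 14 mouse lists past the camera test with the preset correlation (horizontal axis, log2 units, with a wider scale for skeletal muscle), one symbol per tumour, controls above Zelnorm in each row, with group means (vertical bars) and SD (horizontal lines). The number of measured genes follows each name. The adipocyte scores of the groups do not overlap (0.04 to 1.31 against -1.23 to -0.15), nor do those of cell proliferation (0.004 to 0.27 against -0.27 to -0.05). The skeletal muscle scores of the Zelnorm tumours run from -4.31 to 3.75.

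The remaining host lists did not pass. Endothelium and angiogenesis genes were lower in 14 of 22 (adjusted p = 0.108), with Kdr, the main receptor of vascular endothelial growth factor, at 185 ± 29.9 CPM in control and 158 ± 26.0 CPM in Zelnorm tumours. Neutrophil genes were lower in 8 of 10 (adjusted p = 0.238) and interferon response genes in 19 of 28 (adjusted p = 0.33). Hypoxia and glycolysis genes were higher in 14 of 20 (adjusted p = 0.28), chemokines and cytokines in 10 of 21 (adjusted p = 0.33) and pericyte and smooth muscle genes in 10 of 16 (adjusted p = 0.637). Nerve and Schwann cell genes (adjusted p = 0.716), dendritic cell genes (adjusted p = 0.838) and MHC class I presentation (adjusted p = 0.883) had medians of -0.07, 0.03 and -0.01 on the log2 scale. The test pointed against the median for dendritic cells (mean -0.08) and against the median of -0.01 for chemokines and cytokines (mean 0.14), and for MHC class I the mean lay just above 0. Of the skin keratinocyte and hair follicle genes, 2 of 22 were measurable (adjusted p = 0.291). Adjusted over the list alone, 0 members passed in any mouse list other than the adipocyte, complement and red blood cell lists. With an estimated correlation 0 of the 27 mouse lists passed, and the directional test of fry called 0 (smallest unadjusted p = 0.0652, adipocytes). The mixed test of fry, which ignores direction and was not used for calls, had its smallest unadjusted p for T cell and NK checkpoints (0.000506).

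Whether tumour cells and host cells responded differently was tested on 11164 gene pairs with the same symbol. Glb1l2 stood first: its mouse log2 fold change was -2.77 and that of human GLB1L2 0.09, a difference of -2.85 (SE 0.34; edgeR interaction adjusted p = 0.0936). FASN differed by -1.15 (SE 0.20), RACGAP1, a regulator of cell division, by -0.72 (SE 0.16), PON1 by -3.35 (SE 0.70) and APOC1 by -2.46 (SE 0.53). In the other direction SIK1, a kinase, differed by 0.88 (SE 0.18), UCK2 by 0.63 (SE 0.16), EDNRA by 1.74 (SE 0.45), FAM53B by 1.46 (SE 0.40) and PDE4B by 0.60 (SE 0.17). The interaction test in edgeR called 0 pairs, with 177 at an unadjusted p under 0.05 where 558 would be expected by chance, and no other tool was run on it. Without MBZ_259 it called 2 pairs, and without MBZ_257 the difference was -4.56 for PON1 and 2.38 for EDNRA.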

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

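No paired analysis was possible because the columns of both tables carry no replicate number, so the replicate numbers of the labels could not be tied to libraries. The restriction to genes whose partner had under 0.1 of their counts and the removal of both NC4 and MBZ_257 were chosen after the data were seen.

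Called human genes went from 0 to 61 without the count filter and to 2 with DESeq2, and called mouse genes from 0 to 2 and to 6, and to 1 with limma-voom. Without the filter the prior degrees of freedom of the edgeR fit went from 5.81 to 180.9 (human) and from 3.96 to 15.01 (mouse). Leaving out 1 library gave 0 to 0 calls in both tables. Called human lists went from 5 to 0 with an estimated correlation and with fry, to 9 with limma-voom, to 2 with genes of low partner counts and to 9 without both NC4 and MBZ_257, with 1 to 10 when 1 library was left out. Called mouse lists went from 14 to 0 with an estimated correlation and with fry, to 7 with limma-voom and to 9 with genes of low partner counts, with 9 to 16 when 1 library was left out (9 without NC4). The mouse share difference ran from -2.79 to 1.35 points without 1 library, with 0.25 without NC4 and 1.35 without MBZ_257 turning its sign, and called pairs from 0 to 2 (2 without MBZ_259).

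Directions that turned, by the direction of the test for lists and by the fitted value for genes, are given with mean or fitted log2 values. A lowest or highest value in brackets is the extreme among the fits that left out 1 library. Without MBZ_254, hypoxia and glycolysis was at -0.0787 (highest 0.387 without MBZ_259) and Gpnmb at -0.0316 (highest 1.23 without NC4). Without MBZ_257, the test of the human interferon list pointed higher although its mean was -0.0281 (lowest -0.445 without MBZ_254), and collagens and matrix was at 0.0558 (lowest -0.44 without MBZ_254). Without NC4, C7 was at 0.43 (lowest -3.36 without NC9). Without MBZ_259, Pvalb was at -7.43 (highest 1.70 without NC4), Ckm at -8.50 (highest 1.52 without NC4) and Tnnc2 at -7.99 (highest 1.31 without MBZ_257). With limma-voom, the test of skeletal muscle pointed higher at a mean of 0.45, H2-DMb2 at -0.0553, C7 at 0.11 and Tnnt1 at 0.0761. Without both NC4 and MBZ_257, complement was at 0.00352, fibroblasts at 0.0923, collagens and matrix at 0.25, C7 at 0.79, Col3a1 at 0.19 and Mmp2 at 0.13. The mean changed sign while the test kept its direction for MHC class II with limma-voom (-0.152) and for skeletal muscle without NC10 (-0.239) and without MBZ_259 (-6.68). Where no cause is given, the cause was not tested. Of the other values of named genes, 1474 kept their direction and side of the threshold and 14 gained a call. Of those of called lists, 234 did and 99 lost the call. All 92 values of named pairs did. No named gene or pair was called in the main fit, so staying uncalled was likely beforehand and is no sign of a robust result. The mouse table, at 5817165 to 9228446 counts per library, recovered 9 of 100 simulated 2-fold changes, so changes of that size would mostly be missed there.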

Other observations

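All tests of this part were chosen after the result they bear on was seen, except the counts of other splits for the gene lists.

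Muscle content differed between single tumours more than between groups. When the 6 libraries were split into 3 and 3 in the 10 possible ways, the split of NC10, MBZ_254 and MBZ_257 against the rest called 46 mouse genes, 12 human genes and 34 gene pairs. Of the human calls 6 were in the skeletal muscle list, and of the mouse calls 5, beside other muscle genes such as Myog and Des, chosen for mention after their values were seen. That split follows the muscle score, which was lowest in these 3 libraries, and points to a structure of the samples. The real split called 0 in each of these counts, which all 10 splits must reach (highest other 12, 46 and 34), so these counts say nothing about chance. At an unadjusted p under 0.05 in edgeR, the real split had 247 human genes, against 377 to 2157 in the other splits. It had 177 gene pairs, against 182 to 1638, and 253 mouse genes, against 207 to 1761. For the lists, 8 of the 10 splits gave at least the real 5 human lists (highest other 8), and 2 gave at least the real 14 mouse lists (highest other 14). With 10 splits no share under 0.05 is possible.

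The lower level of adipocyte genes in the Zelnorm tumours is the pattern most open to follow-up. The 8 members whose same-symbol human partner had under 0.1 of their counts, or was lacking, argue against human reads in the mouse table. They were all lower, with a median log2 fold change of -1.52. Scd1 and Car3 are among these 8, but their human genes carry other symbols, so for them the test cannot decide. The pattern did not rest on 1 library, since the mean of the list stayed at -0.87 or lower without each library. More neighbouring tissue in the control samples may still be the cause: the skeletal muscle score differed by -2.97 between Zelnorm and control tumours, within the SD of 4.53 of the Zelnorm group, so a difference in dissection cannot be told apart from a loss of fat cells or of their transcripts under treatment. Tumour by tumour, MBZ_259 had the highest muscle score (3.75) and the lowest adipocyte score (-1.23) and the control NC10 a muscle score of -0.35. Mean scores of fibroblast, mast cell and red blood cell genes were also lower in the Zelnorm group, but single tumours did not follow the fat genes. MBZ_259 had a fibroblast score of 0.05, against 0.04 in NC10 and 0.05 in NC9. MBZ_254 had a mast cell score of 0.16, against -0.14 in NC10, and both had a red blood cell score of -0.29.

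Muscle myosins in the human table are a candidate sign of mouse reads counted as human. MYH1, MYH2 and MYH4 together had 224 to 5524 human-table counts in the 4 libraries with mouse muscle counts, and 0 and 2 in MBZ_254 and MBZ_257, where the mouse table had 11 and 4. The highest of these was 0.085% of the median of the other libraries. Expression by the tumour cells is hard to hold against the share of myosin counts placed in the human table. In the 4 libraries with mouse muscle counts that share stayed between 21.6% and 26.5%, a ratio of 1.23, while the human-table counts varied 24.7-fold. In the other direction KRT8, abundant in DU145 cells, had 10.7% as many counts in the mouse as in the human table, and EPCAM 0.0216%.

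H2-Eb1 (chromosome 17, 34305867 to 34316674 in GRCm38) was near absent in NC10 and MBZ_259, and a host variant in the MHC region may underlie this. Beside H2-Eb1, which prompted the test, 5 genes were lower in both libraries than in each other library by at least 2 log2 units, and 3 of them (H2-Ea-ps, H2-Q2 and Gm10499) lay in the region from H2-K1 to H2-M3, which holds 121 of 14452 genes. The other 14 pairs of libraries gave 0 such genes in this region. Little antigen presentation in these tumours is argued against by H2-Aa, H2-Ab1 and Cd74, which were on average higher there by 0.37 on the log2 scale. The labels give the hosts only as nude mice, so strain was not tested.

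Gm20388, a locus annotated across several genes on chromosome 8 (119910841 to 124345722), had 448, 1288 and 90868 counts in the controls and 62758, 12813 and 1362 in the Zelnorm libraries.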
